A study of Homo sapiens with 8 samples.

How the data were processed

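RNA of undifferentiated human pluripotent stem cells was sequenced in 8 libraries. WTC11, an induced pluripotent stem cell line, gave 2 control and 3 KIF3B knockout libraries, and WA09, an embryonic stem cell line, gave 2 control and 1 KIF3A knockout library. Groups were taken from the labels, which also number the guide RNA behind each library: guides 1 and 2 in WTC11 and guide 1 in WA09. The cells were untreated, were grown without feeder cells in mTeSR1 medium and were lysed directly. Between 100 and 1000 cells went into each library, prepared with SMART-Seq chemistry and Nextera XT, per the labels' protocols. The series text speaks of several clones, and the labels do not say that each library came from a clone or culture of its own. Where libraries shared one, p-values measure only the spread between these libraries, which may be technical.

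The authors deposited a table of whole-number read counts per gene, not normalized, with 1 column per library and 58302 genes. STAR and the genome build hg38 are named in the submitters' processing notes, without a version of the aligner. The gene counter, the annotation release, the treatment of duplicate reads and of reads that map to several places are not given in the sources used here. The ribosomal protein, histone, tubulin and mitochondrially encoded genes have pseudogenes or near-identical copies, so their counts are uncertain in how such reads were assigned, and genes that overlap on opposite strands cannot be separated. The table gave no gene name for 20993 entries, which held 0.446% to 0.673% of the counts of a library, and 20810 of these were named by identifier. Gene names, positions and transcript lengths came from GENCODE release 29 on GRCh38, to which 58039 entries matched by identifier. All entries stayed in the total counts given for each library, while the edgeR fits described below used totals over the genes tested.

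Total counts ranged from 2161890 to 2875163 per library, so that 3 counts, the limit that a count of 0 allows, correspond to 1.04 to 1.39 CPM, the counts scaled to a common library total. These limits use the totals over all entries, whereas CPM given for genes use totals over the genes tested, with TMM scaling. Such limits cover counting error only. Counts of abundant transcripts levelled off: the highest mean count per base of the longest transcript was 1.46, in MT-RNR2, 7 genes with a mean count of at least 100 lay above 1 count per base, and 0 of 6519 lay above 2. ACTB counts stayed between 2368 and 2586 although library totals differed by a factor of up to 1.33. Not all abundant transcripts were this even: DNMT3B, at 0.769 counts per base, ran from 2467 to 4222 counts. Counts that level off compress the fold changes of abundant transcripts and give a lower CPM in a library with a larger total. Within groups, all 5 pairs of replicate libraries differed by more than sampling noise (chi-square per degree of freedom 5.89 to 9.00). Amplified libraries exceed that noise even as technical repeats, so this does not show that they are separate replicates, as which they were used.

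Differential expression was tested with edgeR 4.0.16 (quasi-likelihood F test with robust estimation, TMM normalization, filterByExpr) in R 4.3.3, and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. The comparisons, the gene lists, the rule for named genes and most alternatives were fixed before the data were examined. In the pooled comparison, 4 knockout were set against 4 control libraries with cell line as an additive term (13238 genes tested). The other 4 comparisons were contrasts in 1 fit with a mean per group (14216 genes tested): KIF3B knockout against WTC11 control, KIF3A knockout against WA09 control, the difference between these effects (KIF3A effect minus KIF3B effect), and WTC11 control against WA09 control. The lone KIF3A knockout library was assumed to vary like the libraries of the other groups, and knocked-out gene and line cannot be separated in this design. Log2 fold changes are given ± SE, and CPM as mean ± SD with n libraries.

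Of genes past the threshold with a mean of at least 5 CPM and no overlap between the groups compared, up to 12 at each end of the fold changes were to be named, together with the targeted genes. Where fewer than 10 genes passed, the 10 with the smallest p were named as not called. For each list, up to 4 members past the threshold, or else the 2 most abundant members, were to be given as values. Other genes named here were chosen after their values were seen, including all that passed only when adjusted over a list alone. XIST and Y-linked genes were left out, and a few genes that the rule names are not reported here.

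The 37 gene lists were tested with camera in limma 3.58.1, with a preset inter-gene correlation of 0.01 and again with the correlation estimated. Members were also counted past the threshold over all genes and adjusted over the list alone. Transcript length was that of a gene's longest transcript. Rank correlations of fold change with length are across genes, which are not independent replicates, and used genes above a log2 CPM of 5. To remove the length trend, a loess curve (span 0.5, genes above a log2 CPM of 4, prior count 2) was fitted to each library's deviation from the mean of all libraries and entered as an offset.

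Alternatives were RLE and upper-quartile normalization, DESeq2 1.42.0, limma voom with sample quality weights, no filter and a stricter filter on low counts, non-robust estimation, mitochondrial genes left out, the number of detected genes as a covariate, fits within 1 line, guide RNA as a replicate block, no line term, and each library left out in turn. The length-trend corrections, alone and with the correlation estimated, and the DESeq2 fits without single WTC11 libraries were added after the data were seen. The rule for library quality was made stricter after the results were seen, and a real count of 0 was then taken to decide nothing in the comparison with other splits. The wording of the DESeq2 thresholds that decide between explanations was changed after the tests from gene numbers to the same fractions.

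The fits were tested on simulated counts with the means and library sizes of the data and 200 changed genes. In the simulated KIF3B comparison (13609 genes), edgeR recovered 9% of 2-fold and 53% of 4-fold changes (22% and 89.6% of those at 50 CPM or more), and 4 of its 66 calls were unchanged genes. DESeq2 recovered 21% and 64%, and 32 of its 117 calls were unchanged genes. For 2-fold and 4-fold changes edgeR recovered 28% and 60% in the simulated pooled comparison (13012 genes), 1% and 24% for KIF3A (13590 genes), 1% and 13% for the difference (13572 genes), and 6% and 32% between lines (13567 genes). This simulation replaced an earlier one that recovered more, because the earlier one had a more uniform spread across genes than the data have. The replacement was still more uniform than the data (prior degrees of freedom 7.42 against 5.86), so recovery may be overstated. A simulated list of 25 genes shifted by 0.5 on the log2 scale was not called by camera (adjusted p = 0.142); a list shifted by 1, added after that miss, was called (adjusted p = 2.57e-24), and 0 of 58 unshifted lists were (13573 genes). Simulated genes varied independently of each other, so these list results do not test calls at the preset correlation in lists whose members vary together. The estimated correlation was not run on simulated lists, so the size of change it can call here is not known. In the data it called 0 lists in every comparison. A list that did not hold with it may still have changed. A simulated length trend with a rank correlation of 0.637 was reduced to 0.02.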

Results

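Kinesin-2 is the motor that carries cargo outward along the primary cilium, and KIF3A and KIF3B are its motor subunits. The 8 RNA-seq libraries set human pluripotent stem cells with either subunit knocked out beside isogenic controls. In WTC11 cells, 3 KIF3B knockout libraries stood against 2 controls. In WA09 cells, 1 KIF3A knockout library stood against 2 controls, so values of that group have no replicate. The WTC11 controls held 2161890 and 2234379 counts, and the KIF3B knockouts 2632475, 2387357 and 2875163. The WA09 controls held 2559733 and 2605256 counts and the KIF3A knockout 2236845. Between 16658 and 18562 genes had at least 1 count in a library, and mitochondrially encoded genes took 0.29% to 0.41% of the counts. The first principal component held 44.9% of the variance between libraries, and the KIF3B knockouts had its highest scores (10.7, 26.4 and 30.5, against -25.1 to 3.4 in the other 5 libraries).

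The targeted genes were examined in every library first. KIF3B RNA (ENSG00000101350, GRCh38 chromosome 20, 32277664 to 32335011) was not reduced in the KIF3B knockouts, which held 41.7 ± 6.58 CPM (SD, n = 3) against 29.6 ± 4.1 CPM (n = 2) in the WTC11 controls. Counts were 129, 86 and 107 in these knockouts and 71 and 59 in their controls, and the log2 fold change was 0.49 ± 0.34 (edgeR adjusted p = 0.507). A knockout allele can leave its RNA in place, so these counts do not check the KIF3B labels, and knockout status rests on them. KIF3A RNA (ENSG00000131437, chromosome 5, 132692628 to 132737638) stood at 33.1 CPM in the KIF3A knockout library and 65.0 ± 4.58 CPM (n = 2) in the WA09 controls, with 75 counts against 174 and 167. This was 50.9% of control, a log2 fold change of -0.97 ± 0.35 that passed the edgeR test adjusted over the 2 targeted genes (adjusted p = 0.0372) and did not pass over all genes (adjusted p = 1). Neither partner subunit passed the test: KIF3A was at -0.20 ± 0.25 in the KIF3B knockouts, and KIF3B at 0.04 ± 0.45 in the KIF3A knockout. A correction for the trend with transcript length described below moved KIF3A to -0.48 and KIF3B to 0.23 in the KIF3B knockouts, neither of them called. The difference between the effects on KIF3A RNA, -0.77 ± 0.42, did not pass either (adjusted p = 0.197 over the 2 genes).

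**Figure D1:**
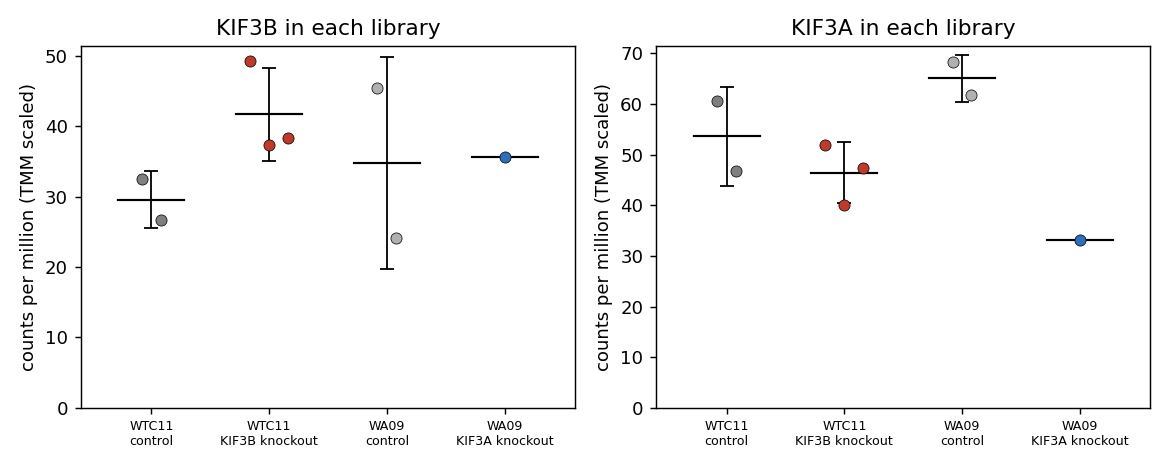
CPM of KIF3B and KIF3A in each of the 8 libraries by group (points), with the group mean (line) and SD (bars, where n is above 1). KIF3B stood at 37.4 to 49.3 CPM in the KIF3B knockouts and 26.7 and 32.5 CPM in their controls, and KIF3A at 33.1 CPM in the KIF3A knockout library, below both WA09 controls.

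The pooled comparison asked which genes differ between knockout and control cells whichever subunit is missing. TEAD1, the transcription factor through which YAP and TAZ act, had a mean of 63.9 ± 5.02 CPM (n = 3) in KIF3B knockouts and 24.4 ± 6.32 CPM (n = 2) in their controls, and of 52.9 CPM in the KIF3A knockout against 33.2 ± 4.61 CPM (n = 2). Its log2 fold change was 1.13 ± 0.24. Other genes with the smallest p were also higher in knockouts: DLG5, a scaffold protein of cell junctions (1.92 ± 0.36), NNT, the mitochondrial transhydrogenase (1.84 ± 0.34), the zinc finger gene ZNF594 (1.80 ± 0.32), the golgin GCC1 (1.74 ± 0.36), C14orf132 (1.38 ± 0.28), the kinase MAP3K4 (1.24 ± 0.25), TRAM2 (1.21 ± 0.25) and AASS of lysine breakdown (0.56 ± 0.11). None of these was called, since the smallest edgeR adjusted p was 0.528. Pooled fold changes had a rank correlation of 0.423 with transcript length. With that trend removed these genes stayed higher at smaller values, such as 0.94 for TEAD1 and 0.53 for AASS. With edgeR 0 of 13238 genes passed, while 1137 had an unadjusted p under 0.05 where 662 would be expected; limma voom called 0 genes and DESeq2 37, all higher in knockouts. The 1137 became 605 without WTC11 control 1, 688 without KIF3B knockout 3 and 2296 without the KIF3A knockout, and 638 with detected genes as a covariate.

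Among gene lists in the pooled comparison, YAP and TAZ targets rose (median log2 fold change 0.67, 15 of 17 higher, camera adjusted p = 0.00241), as did matrix and adhesion genes (0.25, 27 of 35 higher, adjusted p = 0.0131) and cholesterol synthesis genes (0.22, 21 of 24 higher, adjusted p = 0.0344). Cytosolic ribosomal protein genes fell (-0.18, 59 of 61 lower, adjusted p = 1.95e-08), as did replication-dependent histone genes (-0.45, 11 of 13 lower, adjusted p = 0.0131). With an estimated correlation none of the 5 held (smallest camera adjusted p = 0.786). That setting called no list in any comparison and was not run on simulated lists. Its lack of calls thus does not show that a list was unchanged. With the length trend of each library removed, YAP and TAZ targets (0.49) and cholesterol synthesis genes (0.17) stayed called at the preset correlation, though not when it was estimated as well (camera adjusted p = 0.845 for each). The other 3 lists were not called with the length trend removed (0.12 for matrix, -0.06 for ribosomal proteins, -0.07 for histones). Mitochondrially encoded genes, at 0.10 and not called as counted, were called at 0.40 with that correction (adjusted p = 2.59e-11) and not when the correlation was estimated as well (adjusted p = 0.845). These pooled medians rest mostly on the KIF3B knockouts. In the KIF3A comparison the median was 0.06 for YAP and TAZ targets, -0.24 for matrix genes (24 of 35 lower), 0.04 for cholesterol synthesis, 0.11 for ribosomal proteins (52 of 61 higher) and -0.05 for histones. Without the KIF3A library the pooled medians were 1.03 for YAP and TAZ targets, 0.50 for matrix genes and -0.35 for ribosomal proteins. The YAP and TAZ call was also lost without WTC11 control 2 (0.32) and stayed without KIF3B knockout 2, at 0.31. The matrix call was lost without WTC11 control 1 (0.19), WTC11 control 2 (0.23) or KIF3B knockout 2 (0.09), and the histone call without WTC11 control 1 (-0.40) or KIF3B knockout 2 (-0.35). The cholesterol call was lost without WTC11 control 1 (0.15), WTC11 control 2 (0.18), KIF3B knockout 3 (0.05) or WA09 control 2 (0.22).

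The KIF3B comparison asked what changes in WTC11 cells without that subunit. CDH1, which encodes the epithelial adhesion protein E-cadherin (chromosome 16, 68737225 to 68835548), had 321 ± 25.8 CPM (n = 3) in knockouts and 181 ± 11.4 CPM (n = 2) in controls, a log2 fold change of 0.82 ± 0.12. DLG5 (chromosome 10, 77790791 to 77926526) had 46.3 ± 3.79 CPM against 8.44 ± 2.32 CPM, a log2 fold change of 2.45 ± 0.36. The other 8 genes with the smallest p were higher too. They were APH1B, a subunit of gamma-secretase (1.65 ± 0.28), TRAM2 of the endoplasmic reticulum (1.54 ± 0.26), the nuclear pore gene NUP188 (1.40 ± 0.23), SMG5 of nonsense-mediated decay (1.12 ± 0.17), the Golgi sorting adaptor GGA2 (1.12 ± 0.18), the secreted matrix protein gene ANOS1 (1.03 ± 0.17), FAR1 of ether lipid synthesis (1.00 ± 0.16) and the splicing helicase AQR (0.90 ± 0.15). All 10 had an edgeR adjusted p of 0.159 and none was called. Their longest transcripts measured 4189 to 9694 bases, against a median of 3585.5 over all tested genes. With the trend with transcript length described below removed, all 10 stayed higher at smaller values, such as 2.16 for DLG5, 0.60 for CDH1 and 0.59 for AQR. All 10 had a higher mean in the knockouts than in the WA09 controls, though FAR1 and APH1B by little. FAR1 held 160 ± 2.55 CPM in knockouts and 159 ± 31.4 CPM in WA09 controls, and APH1B 60.9 ± 6.12 and 56.6 ± 5.73 CPM. Over all tested genes, 16.5% had every knockout above both controls and 18% every knockout below both, where chance gives 10% each. Genes share trends such as that with length, so 1 split can lie far from 10% without a knockout effect.

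With edgeR 0 of 14216 genes passed in the KIF3B comparison, while 2366 had an unadjusted p under 0.05 where 711 would be expected. Limma voom called 0 genes, and DESeq2 246, of which 228 were higher and 18 lower. DESeq2's higher genes had a median transcript length of 5716.5 bases, against 3585.5 for all tested genes. Its count was 68 without WTC11 control 1, 384 without WTC11 control 2 and 32 without KIF3B knockout 3; with the length trend removed it was 139. The 246 genes had a median log2 fold change, in the direction called, of 1.14 with all libraries, 0.92 with the length trend removed and 1.02 to 1.26 with 1 WTC11 library left out. The number of genes with an unadjusted p under 0.05 in edgeR was 1306 without WTC11 control 1, 1555 without KIF3B knockout 3 and 899 with detected genes as a covariate, and edgeR called 5 genes without WTC11 control 2.

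**Figure D2:**
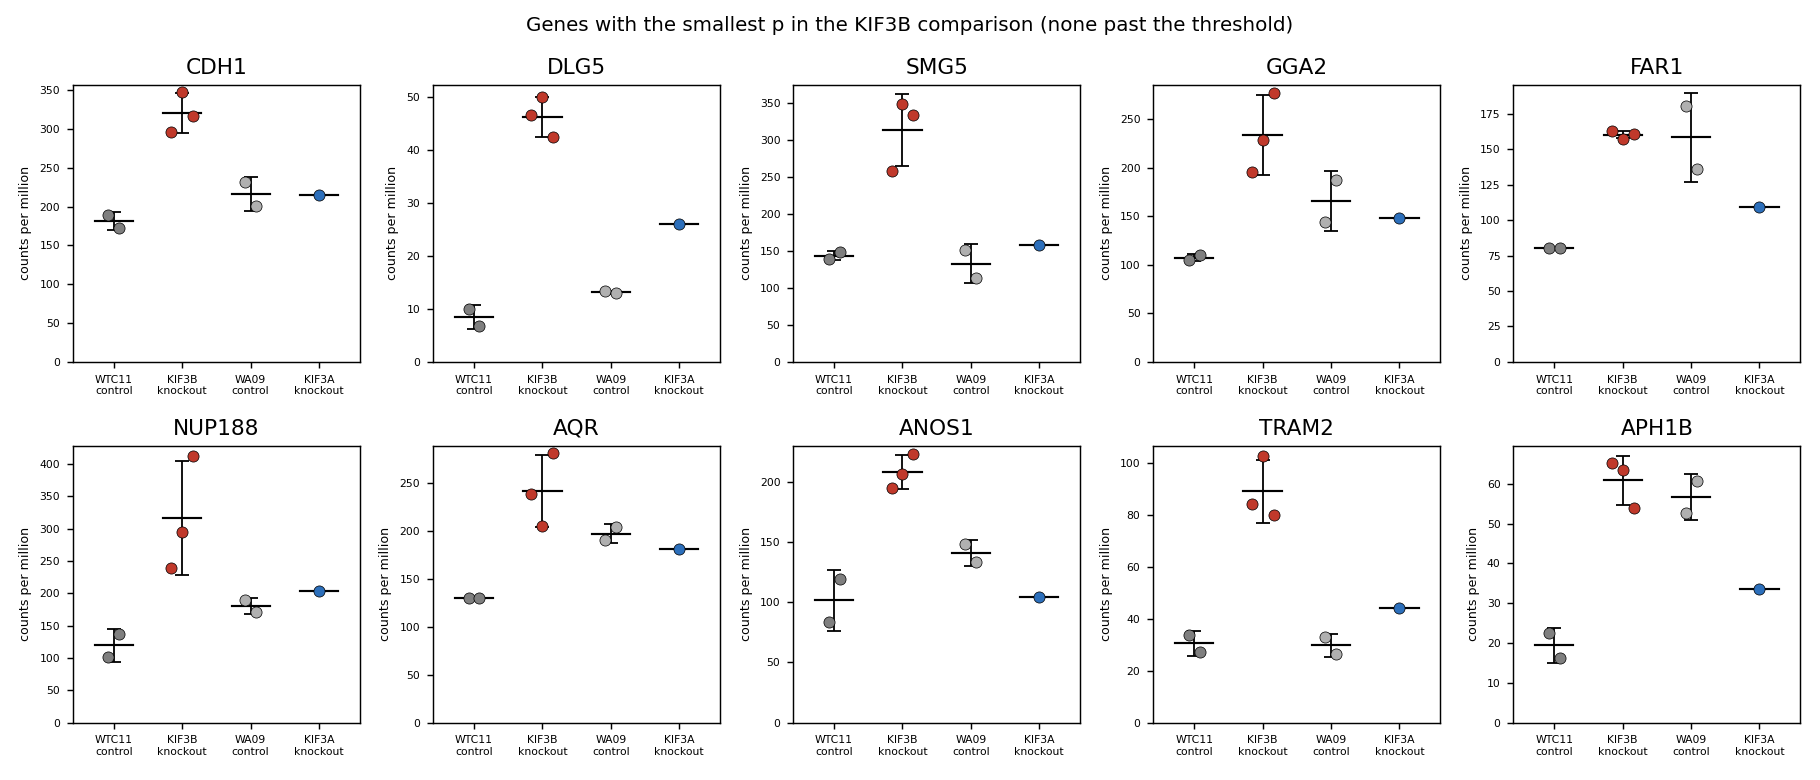
CPM of the 10 genes with the smallest p in the KIF3B comparison, per library (points) with group mean (line) and SD (bars, where n is above 1), in all 4 groups. CDH1 stood at 321 ± 25.8 CPM in the KIF3B knockouts, 181 ± 11.4 CPM in WTC11 controls and 216 CPM in both WA09 groups.

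YAP and TAZ targets, the genes of the Hippo pathway's transcriptional arm, rose in the KIF3B knockouts by a median of 1.04 on the log2 scale, with 15 of 17 members higher (camera adjusted p = 0.000342, and 0.898 with an estimated correlation). With the length trend removed the median was 0.79, still called at the preset correlation (camera adjusted p = 0.000419). It was not called when the correlation was estimated as well (adjusted p = 0.983). CYR61 had 188 ± 91.9 CPM (n = 3) against 88.3 ± 15.2 CPM (n = 2), and CTGF 231 ± 101 CPM against 156 ± 26.5 CPM. Neither passed. In the WA09 controls (n = 2) CYR61 held 141 ± 29.8 CPM and CTGF 244 ± 10.1 CPM, so the WTC11 controls were the low group for both. TEAD1 rose by 1.39 ± 0.28 when adjusted over the list alone (adjusted p = 0.00994). Matrix and adhesion genes rose by a median of 0.50, with 28 of 35 higher (adjusted p = 0.000178), and by 0.23 with the length trend removed (adjusted p = 0.0141). In that list CDH1 and the laminin gene LAMB1, at 105 ± 30.7 CPM against 47.4 ± 0.909 CPM, rose when adjusted over the list alone (adjusted p = 0.00177 and 0.0334). Cholesterol synthesis genes rose by a median of 0.32 (18 of 24 higher, adjusted p = 0.0376), and by 0.29 with the length trend removed (adjusted p = 0.0141). None of the 7 lists called in this comparison held with an estimated correlation (smallest camera adjusted p = 0.898 as counted and 0.983 with the length trend removed). Over all genes 0 members of any list passed.

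Cytosolic ribosomal protein genes fell in the KIF3B knockouts, to a median of -0.34, with 60 of 61 lower (adjusted p = 3.47e-18, and 0.898 with an estimated correlation). In that list 33 members fell when adjusted over the list alone; RPS24, with the largest fall among them, had 148 ± 13 CPM (n = 3) against 220 ± 17.6 CPM (n = 2). Replication-dependent histone genes fell (median -0.49, 12 of 15 lower, adjusted p = 0.00503), with HIST1H1B at -1.10 ± 0.29 and HIST1H4C at -0.42 ± 0.11 past the threshold over the list alone. Interferon response genes fell (median -0.29, 15 of 19 lower, adjusted p = 0.0271). B2M, the light chain of class I antigen presentation, fell by 0.56 when adjusted over that list alone. Immediate early and heat shock genes fell (median -0.15, 15 of 19 lower, adjusted p = 0.0376), with the chaperone HSP90AA1 at -0.43 ± 0.10 past the threshold over the list alone. None of these 4 calls held with an estimated correlation (adjusted p = 0.898 with an estimated correlation for each). With the length trend removed, the histone (0.01), interferon (-0.01) and immediate early (-0.15) lists were no longer called, and the ribosomal proteins, at -0.15, stayed called only at the preset correlation. Mitochondrially encoded genes, at -0.07 and not called as counted, were called at 0.40 with that correction (adjusted p = 1.43e-06) and not when the correlation was estimated as well (adjusted p = 0.983).

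Several of these calls ended with 1 library fewer, most of them at a median about as large as before. Leaving out WTC11 control 2 ended the calls of YAP and TAZ targets (0.74), cholesterol synthesis (0.41), immediate early (-0.19) and interferon genes (-0.30). Leaving out WTC11 control 1 ended those of cholesterol synthesis (0.28), immediate early (-0.06), interferon (-0.31) and histone genes (-0.44). Without KIF3B knockout 3 the cholesterol synthesis (0.02) and interferon lists (-0.13) were not called, and without KIF3B knockout 1 the immediate early list (-0.21). In proportion, the medians that shrank most were those of the cholesterol and interferon lists without KIF3B knockout 3, and of the immediate early list without WTC11 control 1. YAP and TAZ targets (0.61) and matrix genes (0.32) stayed called without KIF3B knockout 2, at lower medians.

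**Figure D3:**
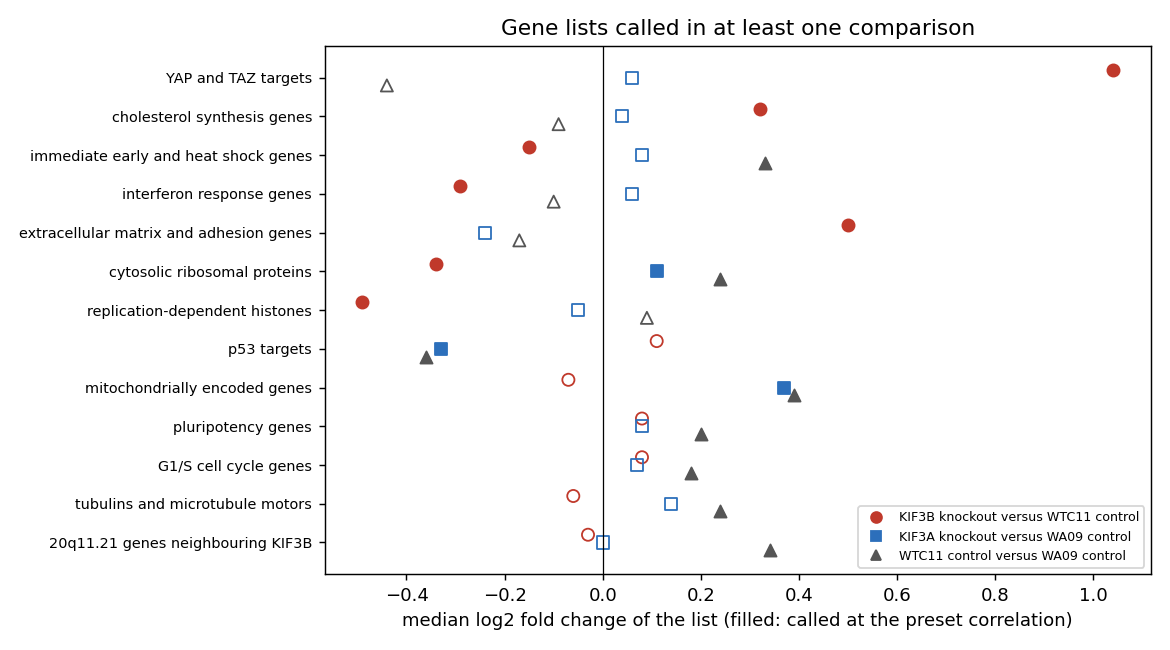
Median log2 fold change of gene lists by comparison, with filled symbols where camera called the list at the preset correlation; none was called with an estimated correlation. YAP and TAZ targets lie at 1.04 in the KIF3B comparison and 0.06 in the KIF3A comparison, and ribosomal protein genes at -0.34 and 0.11.

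Genes of the cilium were not called as lists in the KIF3B knockouts. The median log2 fold change was 0.49 for kinesin-2 subunits (4 of 5 higher), 0.03 for intraflagellar transport (16 of 32 higher), -0.15 for the BBSome and transition zone (20 of 31 lower) and 0.00 for ciliary membrane and signalling proteins (8 of 15 higher). Within them, adjusted over the list alone, NPHP4 of the transition zone rose, from 3.42 ± 0.295 CPM (n = 2) to 28 ± 10.4 CPM (n = 3). GPR161, a ciliary receptor that restrains Hedgehog signalling, rose from 5.23 ± 1.57 CPM to 34.2 ± 7.09 CPM. It stood at 35.5 ± 14.1 CPM in the WA09 controls and 24.7 CPM in the KIF3A knockout, so the WTC11 controls were the low group. EFCAB7, a ciliary protein that acts with the receptor Smoothened, fell from 20.3 ± 1.13 CPM to 3.80 ± 1.06 CPM. Their edgeR adjusted p over the list alone was 0.00819, 0.00235 and 0.0109. Abundant members did not pass, such as IFT57 at -0.28 ± 0.17 and ARL3 at -0.44 ± 0.21.

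Signalling lists other than YAP and TAZ targets were not called in the KIF3B knockouts. Median log2 fold changes were 0.45 for Hedgehog pathway targets, 0.90 for the 3 direct Hedgehog readouts, 0.71 for canonical Wnt targets, 0.31 for planar cell polarity, -0.08 for Nodal and TGF-beta, -0.21 for BMP, 0.12 for Notch and -0.03 for FGF and ERK targets. NOTCH3 rose over its list alone, from 134 ± 10.7 CPM (n = 2) to 218 ± 34.3 CPM (n = 3, adjusted p = 0.0143). DUSP6, a feedback inhibitor of ERK, stood at 192 ± 63.3 CPM against 313 ± 79.5 CPM and did not pass.

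Pluripotency genes were not called as a list (0.08, 15 of 26 higher), and naive pluripotency genes had a median of -0.01. DNMT3B, the de novo methyltransferase, held 1560 ± 138 CPM (n = 3) in the KIF3B knockouts and 1460 ± 197 CPM (n = 2) in controls. Over the list alone CDH1, PODXL (0.79 ± 0.20), SALL4 (0.63 ± 0.14), LIN28B (0.63 ± 0.18) and TRIM71 (0.53 ± 0.13) rose and L1TD1 fell (-0.39 ± 0.10). Lineage markers had medians of -0.07 for primitive streak and mesoderm, 0.22 for definitive endoderm, -0.42 for neuroectoderm, 0.70 for neural crest, 0.16 for trophectoderm and amnion, and 0.33 for fibroblast and mesenchymal markers, and none was called. Cell cycle lists lay at 0.08 (G1/S) and -0.06 (G2/M), p53 targets at 0.11, the unfolded protein and integrated stress response at 0.07, hypoxia and glycolysis genes at 0.05, and tubulins and microtubule motors at -0.06. Imprinted genes lay at 0.20, with the antisense transcript KCNQ1OT1 at 2.25 ± 0.53 past the threshold over the list alone. Neighbours of KIF3B at 20q11.21 lay at -0.03 and those of KIF3A at 5q31.1 at -0.10, where UQCRQ of respiratory complex III fell by 0.63 over the list alone. Mean and median had opposite signs for the Nodal, naive pluripotency, mesoderm, endoderm, tubulin and 5q31.1 lists, and for intraflagellar transport the test's direction was down with both above 0. The smallest camera adjusted p among the 30 uncalled lists was 0.204.

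Long transcripts were higher and short ones lower in the KIF3B knockouts. Genes with transcripts of up to 1000 bases had a median log2 fold change of -0.46 (198 genes), and those above 6000 bases one of 0.23 (1401 genes). Across 7425 genes the rank correlation of fold change with transcript length was 0.487. In single libraries the correlation of the deviation from the mean of all 8 with length was 0.27, 0.372 and 0.421 in the KIF3B knockouts, -0.28 and -0.194 in the WTC11 controls, -0.06 and -0.288 in the WA09 controls and -0.303 in the KIF3A knockout. Most called lists lay in the direction of this trend. The median transcript length was 666 bases in the histone list, 1962 in the ribosomal protein list, 2051 in the interferon list and 2483 in the immediate early list, which fell. It was 4521 in YAP and TAZ targets and 6494 in the matrix list, which rose. YAP and TAZ targets, at 1.04, lay far above the median of 0.18 of genes of 4000 to 6000 bases. Also off the trend were mitochondrially encoded genes (784 bases) at -0.07 and cholesterol synthesis genes (3133.5 bases) at 0.32. The correlation was -0.041 after the trend of each library was removed.

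**Figure D4:**
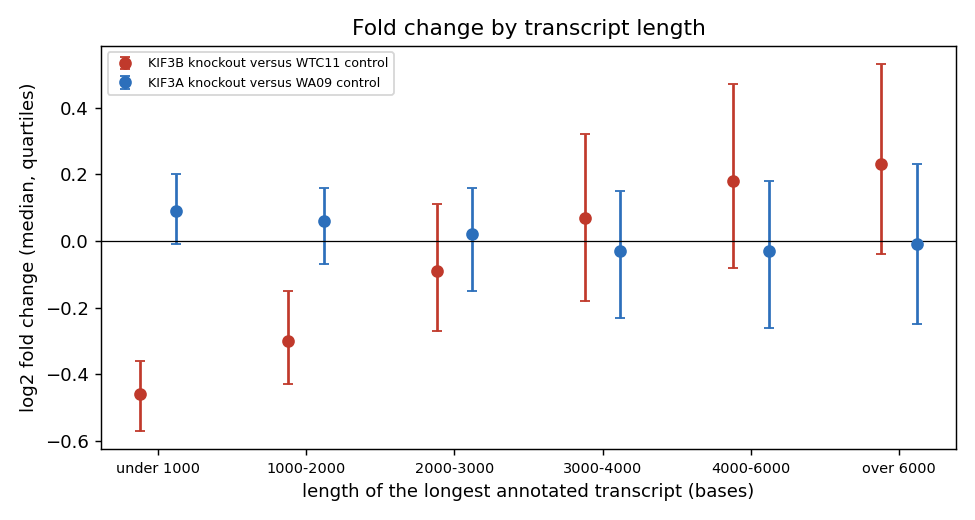
Median log2 fold change (points) with quartiles (bars) of genes grouped by length of the longest transcript in bases, for the KIF3B and KIF3A comparisons. In the KIF3B comparison the medians run from -0.46 in the shortest to 0.23 in the longest group, and in the KIF3A comparison from 0.09 to -0.01.

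The KIF3A comparison asked the same of WA09 cells, with 1 knockout library. Besides KIF3A itself, PRRC2C, which encodes an RNA-binding protein, had 220 CPM in the knockout against 101 ± 20.1 CPM (n = 2), a log2 fold change of 1.12 ± 0.19. PRRC2C held 241 ± 26.1 CPM (n = 2) in WTC11 controls and 249 ± 9.54 CPM (n = 3) in KIF3B knockouts, so the WA09 controls were the low group. ASXL2, a chromatin regulator, was at 2.29 ± 0.49, with the WA09 controls low as well (8.86 ± 4.21 CPM, n = 2). The WTC11 controls held 38.8 ± 9.98 CPM of ASXL2 (n = 2). GAB1, an adaptor of receptor tyrosine kinases, was at 3.10 ± 0.68. Lower values were seen for ZFP1 (-2.79 ± 0.63), BTBD2 (-1.73 ± 0.34), LYSMD3 (-1.61 ± 0.37) and ARSJ, a sulfatase gene (-3.52 ± 0.80). SNX30 and the amino acid transporter SLC36A1 had 0.882 CPM each in the knockout, below the level of 3 counts, against 16.5 ± 4.97 and 17.2 ± 4.40 CPM, and MFSD6 was at 0 against 8.95 ± 0.102 CPM. None of these 10 genes with the smallest p was called by edgeR (adjusted p = 1), which passed 0 of 14216 genes with 527 at an unadjusted p under 0.05, where 711 would be expected. Limma voom called 0 genes and DESeq2 1, PRRC2C.

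The 13 mitochondrially encoded genes were all higher in the KIF3A knockout (median 0.37, camera adjusted p = 7.4e-06) and rose as a list, with MT-CYB at 394 CPM against 291 ± 54.7 CPM (n = 2). Their summed uncorrected counts differed by 0.15 on the log2 scale. Targets of p53 fell (median -0.33, 23 of 27 lower, adjusted p = 0.00173), with CCNG1 at 489 CPM against 530 ± 11.5 CPM. Ribosomal protein genes rose by a median of 0.11 (52 of 61 higher, adjusted p = 0.0164). None of the 3 calls held with an estimated correlation (adjusted p = 0.967 with an estimated correlation). The same 3 lists also differed in the same direction between the WTC11 and WA09 controls, as given below. The WA09 controls enter both comparisons. Their level may thus account for these differences and cannot be told apart from an effect of the knockout. Without WA09 control 1 the p53 median was -0.55, and the mitochondrial list (0.16) and the ribosomal list (0.11) were not called. The ribosomal list was also not called without WTC11 control 2 or with the length trend removed (0.07). Over the list of tubulins and motors alone the kinesin genes KIF16B, at 3.97 CPM against 20.5 ± 1.84 CPM, and KIF13B, at 0 against 10.3 ± 1.19 CPM, fell (adjusted p = 0.0495 for each). Kinesin-2 subunits (-0.21), intraflagellar transport genes (0.03), YAP and TAZ targets (0.06) and matrix genes (-0.24, 24 of 35 lower) were not called. Across 7426 genes the KIF3A and KIF3B fold changes had a Pearson correlation of -0.037, and of 0.011 with the length trend removed.

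The difference between both effects asked whether the knockouts act unequally, although gene and line differ together. Genes with the smallest p had a higher value for the KIF3B than for the KIF3A effect: BCR (-1.70 ± 0.29), FAR1 (-1.54 ± 0.27), the adhesion receptor gene ADGRA3 (-1.52 ± 0.29), APH1B (-2.40 ± 0.46), LYSMD3 (-2.41 ± 0.45), CMTR2 of mRNA capping (-2.46 ± 0.46), ENTPD4 (-2.95 ± 0.56) and NPHP4 (-5.08 ± 0.94). SNX30 and KIF13B were the other 2, at or under 3 counts in the KIF3A knockout. Each of these genes had a lower mean in the WTC11 than in the WA09 controls, so unequal control levels enter these values. FAR1 held 80.2 and 159 CPM in these controls, and CMTR2 20.3 and 62.7 CPM. None was called (edgeR adjusted p = 0.494): edgeR passed 0 of 14216 genes, with 1322 at an unadjusted p under 0.05 (803 without WA09 control 1), limma voom called 0 and DESeq2 17. As lists, YAP and TAZ targets (-1.02, adjusted p = 0.0192) and matrix genes (-0.75, adjusted p = 0.00048) had lower, and ribosomal protein (0.47, adjusted p = 7.33e-17) and mitochondrially encoded genes (0.42, adjusted p = 0.00048) higher effects of KIF3A than of KIF3B. None held with an estimated correlation (adjusted p = 0.979 with an estimated correlation). The YAP and TAZ call was lost without WTC11 control 2 (-0.75) or KIF3B knockout 2 (-0.77), and the mitochondrial one without WA09 control 1 (0.23). With the length trend removed the mitochondrial median turned to -0.16 and was not called, and the others were -0.80 for YAP and TAZ targets, -0.49 for matrix and 0.24 for ribosomal protein genes. With that correction 4 lists were called at the preset correlation, so a list outside these gained a call.

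The control libraries of both lines gave a scale for these effects. PRRC2C (chromosome 1, 171485551 to 171593511) had 241 ± 26.1 CPM (n = 2) in WTC11 and 101 ± 20.1 CPM (n = 2) in WA09, EIF5, a translation initiation factor (chromosome 14, 103333544 to 103345025), 384 ± 11.1 and 186 ± 17.4 CPM, and LARP1, a regulator of ribosomal protein mRNAs (chromosome 5, 154712902 to 154817607), 285 ± 24.5 and 145 ± 5.31 CPM. The low PRRC2C level in the WA09 controls also sets its difference in the KIF3A comparison. GALNT3, a glycosyltransferase (chromosome 2, 165747591 to 165794682), had 39.2 ± 0.314 CPM in WTC11 and 132 ± 18.7 CPM in WA09. These 4 genes passed in edgeR (log2 fold changes 1.26 ± 0.16, 1.05 ± 0.12, 0.98 ± 0.12 and -1.75 ± 0.22, adjusted p = 0.0499 for each), and 2129 had an unadjusted p under 0.05 (1402 without WA09 control 1). Not called were ZC3HAV1 (1.36 ± 0.18), the Polycomb methyltransferase EZH2 (1.34 ± 0.21), SLTM (1.15 ± 0.17), TOP1 (1.06 ± 0.17), DNMT3A (0.89 ± 0.14) and CCAR1 (0.86 ± 0.13). The count was 0 with RLE normalization, a stricter filter, non-robust estimation, mitochondrial genes left out or detected genes as a covariate, 1 with limma voom and 219 with DESeq2 (114 higher, 105 lower in WTC11). Leaving out any 1 of the 8 libraries left 0 or 1 gene.

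Of the lists, 8 were called between the lines. Higher in WTC11 were ribosomal protein genes (median 0.24, adjusted p = 2.63e-07, while their summed uncorrected counts differed by -0.03), mitochondrially encoded genes (0.39, adjusted p = 0.000107, with summed counts differing by 0.12), 20q11.21 genes (0.34, adjusted p = 0.00577), tubulins and motors (0.24, adjusted p = 0.00832), and immediate early (0.33), G1/S (0.18) and pluripotency genes (0.20), the last 3 with an adjusted p of 0.023. Targets of p53 were lower (-0.36, adjusted p = 0.023). None held with an estimated correlation (adjusted p = 0.878 with an estimated correlation). Over the list alone, OTX2 (1.36 ± 0.32) and PRDM14 (0.81 ± 0.20) of the pluripotency genes were higher in WTC11, and LEFTY2, a Nodal antagonist, was lower at 14.8 ± 2.14 CPM (n = 2) against 74.3 ± 12 CPM (n = 2). GPR161 was also lower in the WTC11 controls (-2.75 ± 0.48, adjusted p = 0.0029 over its list alone), the same libraries behind its rise in the KIF3B knockouts. Each call other than that of the ribosomal list was lost on leaving out 1 control library: WA09 control 2 for pluripotency (0.19), G1/S (0.06), p53 (-0.35) and immediate early genes (0.26), WTC11 control 1 for p53 (-0.28), immediate early (0.15) and tubulin genes (0.19), WTC11 control 2 for pluripotency (0.04), G1/S (0.17) and 20q11.21 genes (0.24), and WA09 control 1 for mitochondrial genes (0.16).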

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

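The tests of library quality, of kinesin-2 loss, of the ribosomal protein counts, of length in each of the YAP and matrix lists and of the fold changes of the genes called by DESeq2, the corrections for transcript length and the DESeq2 fits without single libraries were chosen after the results were seen. For 4 gene lists the effect of the KIF3A knockout differed from that of the KIF3B knockout in the camera test of the difference, before the correlation was estimated. The median log2 difference was -1.02 for YAP and TAZ targets, -0.75 for matrix and adhesion genes, 0.42 for mitochondrially encoded genes and 0.47 for cytosolic ribosomal protein genes. These became -0.80, -0.49, -0.16 (adjusted p = 0.8) and 0.24 with the length trend removed, and the mitochondrial call was also lost without WA09 control 1 (0.23). None held with an estimated correlation (adjusted p = 0.979 with an estimated correlation). Knocked-out gene and cell line differ together here, and the KIF3A side rests on 1 library.

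Long transcripts were higher in the KIF3B knockouts, with a rank correlation of fold change and length of 0.487 across genes. Library quality and loss of kinesin-2 both stay open, since the lowest KIF3B knockout lay 0.464 above the highest WTC11 control, libraries of one group ranged by up to 0.228, and the -0.086 of the KIF3A comparison comes from 1 library and ranged from -0.172 to 0.045 with 1 control left out. A ceiling on counts of abundant transcripts cannot be told apart, because genes far from it kept a correlation of 0.198 (3047 genes), between the bounds set for either answer. The 246 genes called by DESeq2 had a median log2 fold change of 1.14 (quartiles 0.83 and 1.64), 0.92 (0.58 and 1.38) with the trend removed and at least 1.02 with 1 library left out, which decides nothing, as they were chosen for large fold changes in all libraries without the correction. Their number leaves the trend open too, since it fell to 139 with the trend removed, between the bounds set. It was 68 without WTC11 control 1, which met the bound set for that library as the cause. This was taken to decide nothing, because leaving out KIF3B knockout 3 gave 32, so the fall is not particular to that control. The number was 384, 312 and 288 without WTC11 control 2, KIF3B knockout 1 and KIF3B knockout 2, with smaller groups, and single libraries stay open.

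YAP and TAZ targets and matrix genes were higher in the KIF3B knockouts, at a median of 0.61 over the 52 genes of both lists. With the length trend removed it was 0.38, and without KIF3B knockout 2, the library with the highest level (0.92 over the WTC11 controls, against 0.33 and 0.53), it was 0.35. Both values lie between the bounds set for and against these explanations. That single library, and length for the matrix genes (0.23 of 0.50 kept), may thus account for part of the difference. They cannot be told apart from an effect of KIF3B loss. On the same scale WA09 control 1 stood at 0.35, WA09 control 2 at 0.09 and the KIF3A knockout at 0.1. The WTC11 controls were thus the lowest group, and 1 library without a knockout reached the level of KIF3B knockout 1. For YAP and TAZ targets alone 0.79 of 1.04 was kept with the fitted trend removed (76.4%, 95% range 72.5% to 118% over resampled members). This lies past the bound set, after the results were seen, against length as the whole cause. The range holds no spread between libraries, members of a list vary together, and the fit used only each gene's longest transcript. A length effect that the fit misses thus stays open. In the KIF3A knockout the YAP and TAZ median was 0.06 and the matrix median -0.24 (24 of 35 lower). That is 1 library of another line and another gene, so it does not decide whether loss of kinesin-2 as such raises these lists.

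Cytosolic ribosomal protein genes were lower in the KIF3B knockouts, with a log2 difference of -0.37 in summed CPM. In this paragraph CPM are scaled to the totals over all entries, without TMM. Their summed uncorrected counts differed by -0.11, while the total counts were higher by 0.26, so a ceiling on counts of abundant transcripts together with unequal library totals is a candidate explanation. The value of -0.11 lies just outside the bound of 0.1 set for it and short of the one set against it, and so leaves it open. In the KIF3A comparison, where the totals differed by -0.21, the summed counts also differed by -0.10 and the CPM by 0.11, and between the WTC11 and WA09 controls totals, summed counts and CPM differed by -0.23, -0.03 and 0.21. The KIF3B median of the list was -0.15 with the length trend removed (camera adjusted p = 0.000108). That call was lost when the correlation was estimated as well (camera adjusted p = 0.983). The fit used only each gene's longest transcript, so a length effect that it misses stays open for this list too.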

How the results depend on the processing

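The corrections for transcript length and the DESeq2 fits without single libraries were chosen after the data were seen. All other alternatives were planned. Counts of called genes under DESeq2 were 37 (pooled), 246 (KIF3B), 1 (KIF3A), 17 (difference) and 219 (lines). With edgeR and no filter on low counts they were 154, 676, 2, 160 and 525; all 676 KIF3B genes were among those tested with the filter, and the prior degrees of freedom were then infinite in place of 5.86. With the length trend removed DESeq2 called 11 (pooled), 139 (KIF3B), 3 (difference) and 253 genes (lines). DESeq2 without WTC11 control 1 or 2 called 68 and 384 genes in the KIF3B comparison, and without KIF3B knockout 1, 2 or 3 called 312, 288 and 32. Between lines, RLE normalization, the stricter filter, non-robust estimation, mitochondrial genes left out and the detection covariate gave 0 genes and limma voom 1; the cause was not tested. Leaving out 1 library at a time gave 0 genes in the pooled, 0 to 5 in the KIF3B (5 without WTC11 control 2), 0 to 1 in the KIF3A (1 without WA09 control 2), 0 to 1 in the difference and 0 to 1 in the line comparison. The number with an unadjusted p under 0.05 in the KIF3B comparison fell to 1306 without WTC11 control 1, and the pooled number ranged from 605, without that library, to 2296. With detected genes as a covariate it was 638 (pooled), 899 (KIF3B), 525 (KIF3A), 771 (difference) and 1067 (lines). With 1 library left out, called lists numbered 3 to 7 (pooled), 3 to 8 (KIF3B), 1 to 3 (KIF3A), 4 to 6 (difference) and 4 to 8 (lines). With an estimated correlation 0 lists were called in each of the 5 comparisons, with or without the length trend, and with the length trend removed 3 in the pooled one. Without the KIF3A library, the KIF3A effect and the difference have no value.

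Guide RNA as a replicate block gave 1 called gene in the KIF3B and 0 in the pooled comparison. Deviations of guide 1 from guide 2 in controls and knockouts had a correlation of 0.029 over 7232 genes. With fewer than 3 pairs this does not decide whether libraries of one guide deviate together. The labels tie the number to a guide RNA.

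Over all alternatives, values of named genes kept their direction and side of the threshold in 989 cases, gained a call in 142, lost one in 56 and turned in 4. Lists did so in 217, lost a call in 98 and turned in 2. KIF3A in the KIF3B comparison turned to 0.01 with DESeq2 without WTC11 control 1. With libraries left out, KIF3B ranged from -0.35 to 0.56 in the KIF3A comparison, from -0.84 to 0.07 in the difference and from -0.62 to 0.28 between lines. The mitochondrial list turned to -0.16 in the difference with the length trend removed, whether the correlation was preset or estimated. At 2161890 to 2875163 counts per library, changes of 2-fold were mostly below what edgeR recovered in simulation.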

Other observations

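The tests of splits and of copy number were planned before their results were seen, and the genes of the first 2 paragraphs were chosen after their values were seen. GLI1, the transcription factor that Hedgehog signalling induces (ENSG00000111087, chromosome 12, 57460135 to 57472262), had 10, 13 and 26 counts in the KIF3B knockouts and 1 and 5 in the WTC11 controls, and 10 counts in the KIF3A knockout against 0 and 2 in the WA09 controls. Every knockout library thus lay above both controls of its line. In the pooled edgeR fit its log2 fold change was 2.57 ± 0.91 (adjusted p = 0.565 over all genes and 0.0484 when adjusted over the list of direct Hedgehog readouts alone). The other tested readouts did not pass over that list: HHIP, a Hedgehog-binding antagonist, was at 1.14 ± 0.82 and the receptor gene PTCH1 at 0.22 ± 0.60. The list as a whole was not called in the pooled comparison (camera adjusted p = 0.0856). GLI1 is also in the longer list of Hedgehog pathway targets and did not pass when adjusted over that list. At these counts the estimates are coarse, and the line and the gene behind each library differ together.

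The core pluripotency factors did not pass the test in any comparison. POU5F1 had 192 ± 13.2 CPM (n = 3) in the KIF3B knockouts and 229 ± 11.4 CPM (n = 2) in their controls, and 249 CPM in the KIF3A knockout against 220 ± 1.32 CPM (n = 2). NANOG stood at 56.5 ± 6.59 and 60.6 ± 1.13 CPM in the WTC11 groups and at 55.1 and 54.7 ± 6.89 CPM in the WA09 groups, and SOX2 at 103 ± 6.97 and 116 ± 5.76 CPM and at 113 and 123 ± 9.97 CPM. Their edgeR adjusted p in the KIF3B comparison was 0.294, 0.851 and 0.613.

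Genes at 20q11.21 (chromosome 20, 31514410 to 33443892), where KIF3B lies, were higher in WTC11 than in WA09. Gains of this region recur in cultured pluripotent stem cells, and a copy number difference between the lines is a candidate explanation. Over all libraries the median log2 difference of 19 genes was 0.36, with 16 higher, at percentile 99 of 690 windows of as many neighbouring genes on other autosomes, 95% of which lay between -0.35 and 0.30. The other 360 tested genes of chromosome 20 had a median of 0.09. Within WTC11, the KIF3B knockouts and controls differed by a median of -0.03. KIF3B itself lies in this interval but was not among the 19 genes. It was not higher in the WTC11 controls, at 29.6 ± 4.1 CPM (n = 2) against 34.8 ± 15.2 CPM (n = 2) in WA09 (log2 difference -0.23 ± 0.37). DNA was not analysed here, and an expression difference of neighbouring genes without a change in copy number stays open.

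The pooled counts were set against other splits of the libraries within lines, 30 with the real one. The real split gave 0 called genes and the highest of the others 0, so that 30 of 30 gave as many. With a real count of 0 no share under 0.05 is possible, and this count tests nothing. Chance could not be excluded for the other two counts. For genes with an unadjusted p under 0.05, 3 of 30 splits reached the real number of 1137, with 1753 as the highest of the others, in the split that puts WA09 control 1 in place of the KIF3A knockout. For called lists, 19 of 30 splits reached the real number of 5, and the highest of the others was 9. The KIF3B split gave 2366 genes at an unadjusted p under 0.05, where the highest of the other splits gave 1890. Of 10 splits 1 reached the real value, and 10 splits cannot give a share under 0.05.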
